A study of Mus musculus with 17 samples.

How the data were processed

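Gene expression was measured in kidneys of 17 male mice aged 16 weeks, 1 library per animal. The db/m animals (n = 8) carry 1 mutant copy of the leptin receptor gene Lepr and served as lean controls. The db/db animals (n = 9) carry 2 mutant copies, lack signalling through the long form of the leptin receptor, and become obese and diabetic. Per the labels' protocols, polyadenylated RNA was made into libraries with a QuantSeq 3′ mRNA kit in the forward orientation, which reads the 3′ end of each transcript, so a count does not grow with transcript length. The same protocol text speaks of RNA from cultured cells in plates, whereas the tissue field and the titles give kidney. The samples were treated as kidney.

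The deposited table holds raw counts per gene for the 17 libraries, made by the authors with STAR 2.7.3a and HTSeq 2.16.2 per the submitters' processing notes. Those notes list the human build GRCh38, while the table's identifiers are mouse Ensembl genes. The mouse build and annotation release, the strand setting and the treatment of molecular identifiers are not given in the sources used here. For that reason no coordinates are printed, only chromosomes, and genes that overlap on opposite strands or share reads with close copies are uncertain. Of 55487 gene identifiers, 55141 were given a symbol from a table of mouse gene names. Identifiers without one held 0.00885% of the counts. The GENCODE M21 annotation was used for chromosomes, for which genes lie near each other, and for GC content only. The table's lines for reads outside genes and for ambiguous reads held 19.3% and 0.533% of all its reads, and were left out of library sizes and tests.

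Groups were taken from the sample titles. The library names and the group sizes in the series design (8 and 9) give the same groups. The genotype characteristic states the opposite genotype for all 17 samples and would give 9 db/m and 8 db/db and was taken as swapped. If it were right and the titles wrong, every direction given here would turn round. Library numbers 1 to 8 are db/m and all db/db libraries have higher numbers, so a batch that followed the library number could not be told apart from the group. No library was a copy of another: the lowest chi-square per degree of freedom between 2 libraries of a group was 3.78.

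Gene counts per library ran from 3256427 to 7627747. Confidence intervals on fold changes are at the 95% level. The limit that a count of 0 allows was taken as 3 counts of a library's total. As duplicate reads may not have been removed, such limits cover counting error only.

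Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust option off) in R 4.3.3, comparing db/db with db/m over all 17 libraries with no covariate. Genes were kept by filterByExpr with its minimum count of 10, which left 12131 genes, and libraries were scaled by TMM. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. All log2 fold changes are db/db minus db/m. CPM values (gene counts scaled to a fixed total with TMM factors) are given as mean ± SD over the libraries of a group; log2 CPM used a prior count of 2. The SE of a log2 fold change is its size divided by the square root of its F statistic. Nnmt had too few counts to pass the filter, so it was fitted together with all 25107 genes that had any count, a departure from the filter set beforehand. DESeq2 1.42.0 and an exact two-sided permutation test of mean log2 CPM were run beside it.

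Fixed lists of genes, 41 in number, covered kidney cell types, other cell types a kidney piece can hold, metabolism, stress, senescence and fibrosis. They were written from general knowledge before the data were examined, as were the tests, the rule for naming genes and most of the other settings tried. The 37 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run beside it; fry asks whether a list's own genes move, on balance, one way. For each list the called members were counted over all genes tested and again adjusted over the list alone. Genes named are Nnmt and Lepr; the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of at least 2, leaving out unnamed and predicted genes; and the 3 members of each list with the smallest p. Some genes that were to be named are not reported here, in the figures or in the search for values that stood far from their group. Other list members, and genes outside the lists, were chosen after their values were seen.

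Nnmt was correlated with the mean z-score of 4 lists within each group, by Pearson's r and Spearman's rho with exact permutation p, two-sided, adjusted over 8 relations. Called genes were counted within 10 Mb of Lepr and elsewhere and compared by Fisher's exact test, two-sided. Library measures were compared between groups by exact permutation tests, two-sided, with SciPy 1.17.1 under Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

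The other settings set before the data were examined were RLE and upper quartile scaling, DESeq2, limma voom, no count filter, a filter of 10 counts in 8 libraries, the robust option, removal of the 20 highest genes or of mitochondrially encoded genes, the replicate number as a block, 1 surrogate variable (sva 3.50.0), stricter thresholds, and each library left out in turn. Those added after the data were seen were offsets adjusted for the GC content of the last 500 bases of the longest transcript (lowess span 0.3), and removal of 4 libraries that stood apart in a principal component analysis or in genes detected: db/m replicate 8 and db/db replicates 4, 7 and 8.

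The procedure was tested on simulated counts for the 12131 genes of this comparison, 200 of them changed. It recovered 29.9% of 67 genes changed 1.5-fold, 70.1% of 67 changed 2-fold and 97.0% of 66 changed 4-fold, and 3.55% of the 141 called genes were unchanged ones. A glycolysis list changed 1.5-fold was found, with 0 other lists. The simulated genes were drawn independently of each other. For lists whose genes move together, the simulation therefore cannot show how often camera calls an unchanged list. It also held no differences between libraries of a group that many genes share. The 3.55% therefore need not hold for the real libraries.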

Results

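Transcripts were counted by 3′ end sequencing in kidneys of 8 db/m mice, which are lean carriers of 1 mutant leptin receptor copy. They were set against those of 9 db/db mice, which lack a working long leptin receptor and are obese and diabetic. All were males aged 16 weeks. Libraries held 3256427 to 7627747 gene counts (4825620 ± 1092210 in db/m and 4467510 ± 1376330 in db/db, mean ± SD; exact permutation p = 0.562, two-sided) and 16102 to 19328 detected genes. Mitochondrially encoded genes took 28.8% ± 1.24 of the counts in db/m and 27.4% ± 2.60 in db/db (exact permutation p = 0.168). Reads outside genes made up 20.2% ± 0.451 of the table in db/m and 18.3% ± 2.29 in db/db (exact permutation p = 0.0360), and ambiguous reads 0.503% ± 0.0222 and 0.567% ± 0.0308 (exact permutation p = 0.000494). The first principal component of log2 CPM held 32.8% of the variance and did not separate the groups (exact permutation p = 0.0981), with db/db replicate 8 at 79.2 and db/m replicate 8 at -44.3. The second held 16.5% and differed between them (exact permutation p = 0.000247). Groups follow the sample titles, which go with the library names and the stated group sizes, whereas the genotype field gives the opposite genotype for all 17 samples. If that field were right, every direction would turn round.

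**Figure D1:**
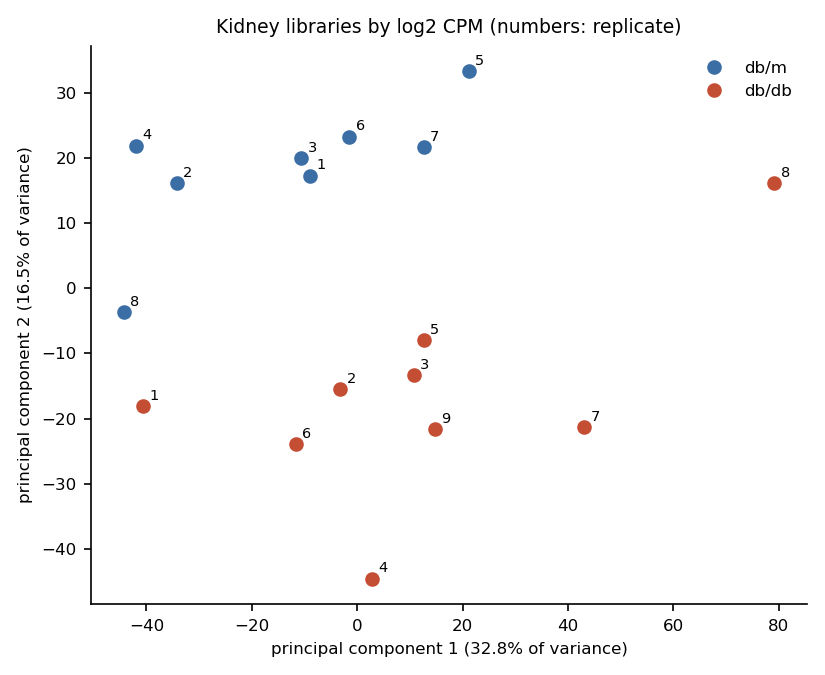
Positions of the 17 libraries on the first 2 principal components of log2 CPM (32.8% and 16.5% of the variance), 1 point per library, numbered by replicate and coloured by group. The group means differ along the second component, though the groups overlap there (db/m replicate 8 at -3.63, db/db replicate 8 at 16.1), while db/db replicate 8 (79.2) and db/m replicate 8 (-44.3) lie at the ends of the first.

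The series title links nicotinamide N-methyltransferase (Nnmt), which methylates nicotinamide with the methyl group of S-adenosylmethionine, to tubular senescence and fibrosis, so Nnmt was examined first. Nnmt was barely detected by this assay: 41 counts over the 8 db/m libraries, 2 of them at 0, and 46 counts over the 9 db/db libraries. Its level was 1.11 ± 0.808 CPM in db/m and 1.06 ± 0.695 CPM in db/db (SD), where 3 counts correspond to 0.380 to 0.929 CPM depending on the library. The log2 fold change was -0.03 (SE 0.57, 95% interval -1.19 to 1.14; adjusted p = 0.991 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and mean log2 CPM differed by 0.07 (exact permutation p = 0.870, two-sided). A difference within that interval was not excluded. Genes that most cells use were nearly absent from the same table: Gapdh had 18 counts over db/m and 25 over db/db, Pgk1 30 and 35, and the mitochondrial mt-Co2 0 and 0. A low count here therefore need not mean low expression. Whether reads of Nnmt, or of the other genes too low to test, were lost as well was not tested. Lepr (chromosome 4) was at 3.77 ± 1.92 CPM in db/m and 1.92 ± 1.42 in db/db, a log2 fold change of -0.97 (SE 0.44) that did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.211). As 3′ tags need not read the mutated part, Lepr does not check the genotype labels.

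**Figure D2:**
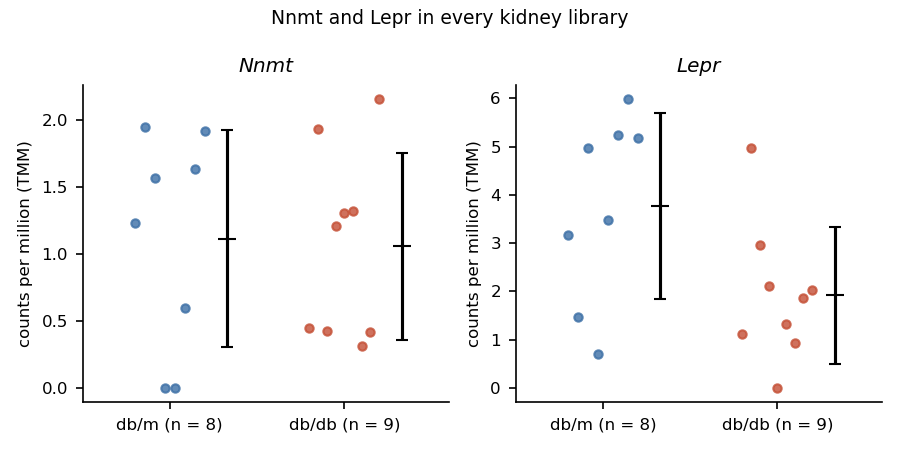
CPM of Nnmt and Lepr in each library (points) with each group's mean ± SD beside them, on linear axes (n = 8 for db/m, n = 9 for db/db). Nnmt lies at 1.11 ± 0.808 CPM in db/m and 1.06 ± 0.695 in db/db, with the groups overlapping.

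Within each group, Nnmt was set against the scores of 4 gene lists: cell cycle arrest and p53 targets, senescence-associated secreted factors, fibrosis and extracellular matrix, and tubular injury. The 8 correlations ranged from r = 0.0683 to r = 0.778, and none passed adjustment over the 8 relations (lowest adjusted p = 0.169). The highest, with tubular injury in db/m (r = 0.778, exact permutation p = 0.0211; rho = 0.563, p = 0.155; n = 8), rested on the 2 libraries farthest from the median of Nnmt, since without them r was 0.139 (exact permutation p = 0.735). In db/db, r with tubular injury was 0.606 (exact permutation p = 0.0815; rho = 0.383, p = 0.313; n = 9), and 0.673 (exact permutation p = 0.0992) without the corresponding 2 libraries. With fibrosis and extracellular matrix, r was 0.628 in db/m (exact permutation p = 0.104; rho = 0.659, p = 0.0850; n = 8) and 0.213 in db/db (exact permutation p = 0.556; rho = 0.20, p = 0.613; n = 9), and without 2 libraries 0.804 (exact permutation p = 0.0792) and 0.634 (exact permutation p = 0.127). With cell cycle arrest, r was 0.242 in db/m (exact permutation p = 0.545; rho = 0.491, p = 0.222; n = 8) and 0.168 in db/db (exact permutation p = 0.667; rho = 0.167, p = 0.678; n = 9), and without 2 libraries 0.110 (exact permutation p = 0.831) and 0.504 (exact permutation p = 0.234). With secreted factors, r was 0.244 in db/m (exact permutation p = 0.541; rho = 0.359, p = 0.379; n = 8) and 0.0683 in db/db (exact permutation p = 0.853; rho = 0.367, p = 0.336; n = 9), and without 2 libraries 0.585 (exact permutation p = 0.231) and -0.520 (exact permutation p = 0.256).

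The comparison of db/db with db/m kidneys asks which transcripts differ with the diabetic genotype. The largest rises were in Bhmt, which remethylates homocysteine from betaine (log2 fold change 5.28, SE 0.51; 0.243 ± 0.332 CPM in db/m and 9.36 ± 5.25 in db/db), the fatty acid hydroxylase Cyp4a14 (4.49, SE 0.44; 18.1 ± 18.9 and 405 ± 114 CPM) and Grem1, a secreted antagonist of bone morphogenetic proteins (4.43, SE 0.51; 0.418 ± 0.340 and 8.65 ± 4.80 CPM). The largest falls were in the organic anion transporters Slc22a26 (-5.02, SE 0.32; 11.5 ± 1.22 CPM in db/m and 0.349 ± 0.292 in db/db) and Slco1a1 (-4.93, SE 0.58; 230 ± 73.0 and 7.51 ± 12.2 CPM) and in the lipoxygenase Alox15 (-4.56, SE 0.28; 34.4 ± 10.3 and 1.44 ± 0.879 CPM). Without db/db replicate 1, Slco1a1 was at -5.95 (SE 0.44), with a db/db mean of 3.81 CPM. Kap, the androgen-regulated kidney protein and a very abundant transcript, fell from 24312 ± 4207 to 4071 ± 1244 CPM (-2.58, SE 0.19). In all, 474 genes were higher and 423 lower in db/db among 12131 tested (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), of which 128 and 167 had an absolute log2 fold change of at least 1.

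Other large rises were glutathione transferase Gsta2 (log2 fold change 4.27, SE 0.30), vitamin D binding protein Gc (3.26, SE 0.35), the prolactin receptor Prlr (2.88, SE 0.25), kynureninase Kynu (2.55, SE 0.29), the glutamine transporter Slc38a3 (2.46, SE 0.18), Camk1g (2.24, SE 0.40) and monoamine oxidase Maob (2.20, SE 0.31). Other large falls were Acsm3 (-3.87, SE 0.34), immunoglobulin heavy chain alpha Igha (-3.80, SE 0.36), the oxysterol hydroxylase Cyp7b1 (-3.78, SE 0.31), the anion transporter Slc22a7 (-3.22, SE 0.32), Pzp (-2.95, SE 0.22), Akr1c14 (-2.84, SE 0.24), the immunoglobulin light chain Igkc (-2.74, SE 0.54) and Cyp4a12a (-2.52, SE 0.21). The groups did not overlap for 10 of the 12 largest rises and 11 of the 12 largest falls. For genes not picked by their values, chance gives non-overlap for 0.00823%. These genes were picked for the size of their change in the same libraries, so that rate does not apply to them. Bhmt in db/m rests on 8 counts, with 4 libraries at 0 and a mean of 0.161 CPM without db/m replicate 7. Grem1 in db/m rests on 14 counts, with 2 libraries at 0, and Slc22a26 in db/db on 13 counts. The folds of these genes are therefore imprecise. Grem1 passed the count filter in only 9 of the 17 fits that left out 1 library. Gsta2, the Cyp4a and Slc22a genes and the immunoglobulins have close copies whose reads the counting could have split.

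**Figure D3:**
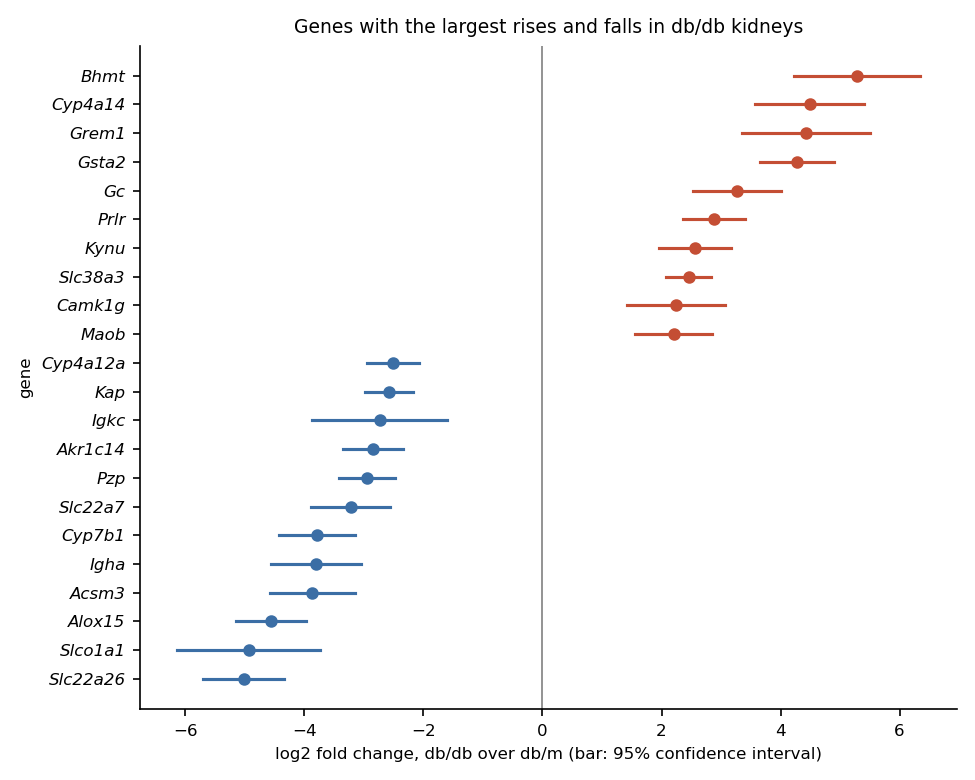
Log2 fold change (db/db minus db/m) of 10 of the 12 largest rises (red) and of the 12 largest falls (blue), with 95% confidence intervals from edgeR. They run from 5.28 for Bhmt to -5.02 for Slc22a26.

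Genes known to be more abundant in male than in female mouse kidney fell as a group: 13 of 13 tested members were lower in db/db, and 13 adjusted over the list alone, with a median log2 fold change of -2.17. Among them, Slc7a13, an amino acid transporter, went from 472 ± 86.8 to 90.0 ± 36.9 CPM and Cyp2j13 from 220 ± 52.0 to 74.7 ± 30.8 CPM. The camera test gave an adjusted p of 2.34e-24, and 0.00995 with an estimated correlation. The calls of Odc1 and Cyp2e1 ended in 9 and 11 of 17 fits that left out 1 library. Of 6 genes known to be more abundant in females, Prlr and Cyp4a14 rose while Slc22a19 (-2.26, SE 0.31) and Cyp2a4 (-2.10, SE 0.36) fell, and the list was not called (2 higher and 3 lower adjusted over the list alone; adjusted p = 0.741; median -0.54, mean 0.32).

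Markers of the last proximal tubule segment, S3, were lower as a group: 5 of 11 fell and 1 rose (7 and 1 adjusted over the list alone). Cyp7b1 and Slc7a13, which are also on the male-biased list, fell, as did Slc22a7, the lipid flippase Atp11a (-1.21, SE 0.15) and the protease Napsa (-0.71, SE 0.11), while the sugar transporter Slc5a10 rose (1.10, SE 0.13). Camera gave an adjusted p of 5.88e-06, and 0.0200 with an estimated correlation. Of 17 markers of the earlier segments S1 and S2, 2 rose and 1 fell (6 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.320). Only 1 rose without db/m replicate 1, 3, 6 or 8 or db/db replicate 4 or 5, and 2 fell without db/db replicate 1. The neutral amino acid transporter Slc6a19 was among the higher (0.93, SE 0.16), and the phosphate and urate transporter Slc17a3 was lower (-1.12, SE 0.14).

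Of the distal nephron lists, 3 were higher in db/db by camera, though the principal cell list was not with an estimated correlation. In the distal convoluted and connecting tubule, 7 of 11 markers rose (8 adjusted over the list alone; camera adjusted p = 4.68e-08, and 0.0255 with an estimated correlation). They included the calcium-binding proteins Calb1 (1.43, SE 0.13; 117 ± 16.7 to 315 ± 62.9 CPM) and S100g (1.02, SE 0.15), the sodium-calcium exchanger Slc8a1 (0.89, SE 0.14) and kallikrein Klk1 (0.58, SE 0.12). The list's members did not rise alike: Slc12a3 lay at only 0.0389 to 0.170 over the 17 fits that left out 1 library. In intercalated cells, which secrete acid or base, 5 of 12 rose (6 adjusted over the list alone), including the proton pump subunits Atp6v1g3 (0.49, SE 0.11) and Atp6v0d2 (0.57, SE 0.14). Their adjusted p by camera was 0.00117, and 0.0284 with an estimated correlation, while 3 were called without db/m replicate 2 or 4 or without db/db replicate 7 or 9. In principal cells, which take up water and sodium, 4 of 10 rose and 1 fell (6 and 1 adjusted over the list alone), with the water channel Aqp2 higher (1.04, SE 0.27) and Aqp4 lower (-0.95, SE 0.24). The call of Aqp2 ended with GC-adjusted offsets, at an edgeR adjusted p of 0.0640, and that of Aqp4 ended at 0.152 with the 4 libraries that stood apart removed. By camera the list had an adjusted p of 0.00717, but adjusted p = 0.217 with an estimated correlation, and 2 members rose without db/m replicate 2, 4 or 6 or without db/db replicate 9. In the thick ascending limb 2 of 11 rose and 1 fell (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.320). Without db/m replicate 2, 3, 4 or 8 or db/db replicate 7, 8 or 9, 1 of these rose. Epidermal growth factor Egf fell there (-0.86, SE 0.13; 359 ± 45.9 to 197 ± 44.9 CPM), and Cldn16 rose (0.78, SE 0.20).

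Of 12 genes of gluconeogenesis, fructose and polyol metabolism, 5 rose (9 adjusted over the list alone), including the fructose transporter Slc2a5 (1.08, SE 0.20), the glucose transporter Slc2a2 (0.62, SE 0.12) and the glucose 6-phosphate transporter Slc37a4 (0.49, SE 0.10). The list's adjusted p by camera was 1.30e-06, and 0.0255 with an estimated correlation. Of 12 glycolytic genes 4 rose (8 adjusted over the list alone), including Pkm (94.5 ± 22.4 to 189.7 ± 59.1 CPM) and Pfkl (0.76, SE 0.17). The list had a camera adjusted p of 3.31e-05, but adjusted p = 0.0598 with an estimated correlation. Of 23 genes of fatty acid oxidation and PPARα targets, 6 rose and 1 fell (8 and 2 adjusted over the list alone), with Cyp4a14 and the thiolase Acaa2 (1.09, SE 0.13) among the higher. Of the 23, 0 fell without db/m replicate 4, and 2 did without db/db replicate 8. As a list these genes had an adjusted p of 0.00336, but adjusted p = 0.208 with an estimated correlation. Of 24 nuclear genes of the respiratory chain, 5 rose (8 adjusted over the list alone), with a list adjusted p of 0.000597, but adjusted p = 0.227 with an estimated correlation. Only 1 was called without db/m replicate 4, 2 without db/m replicate 1, 2, 6 or 8, and 3 without db/m replicate 3 or db/db replicate 5 or 7. In the methionine cycle 3 of 15 rose, Bhmt among them, and 2 fell (3 and 2 adjusted over the list alone). The list was not called by camera (adjusted p = 0.320), whereas fry called it higher (adjusted p = 0.0421). Bhmt was the 1 higher gene left without db/m replicate 2, 3, 4 or 8 or without db/db replicate 5 or 7, and 1 gene fell in 13 of 17 fits that left out 1 library. Mat2a, which makes S-adenosylmethionine, was lower (-0.53, SE 0.12). Of 18 genes of NAD synthesis and use, Kynu alone was called (1 adjusted over the list alone; list adjusted p = 0.875). In cholesterol synthesis, 2 of 17 fell, Cyp51 among them (-1.32, SE 0.16), and 0 rose (3 higher and 3 lower adjusted over the list alone). Positive values were seen for 14 of the 17, and the list was not called (median 0.27, adjusted p = 0.393).

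**Figure D4:**
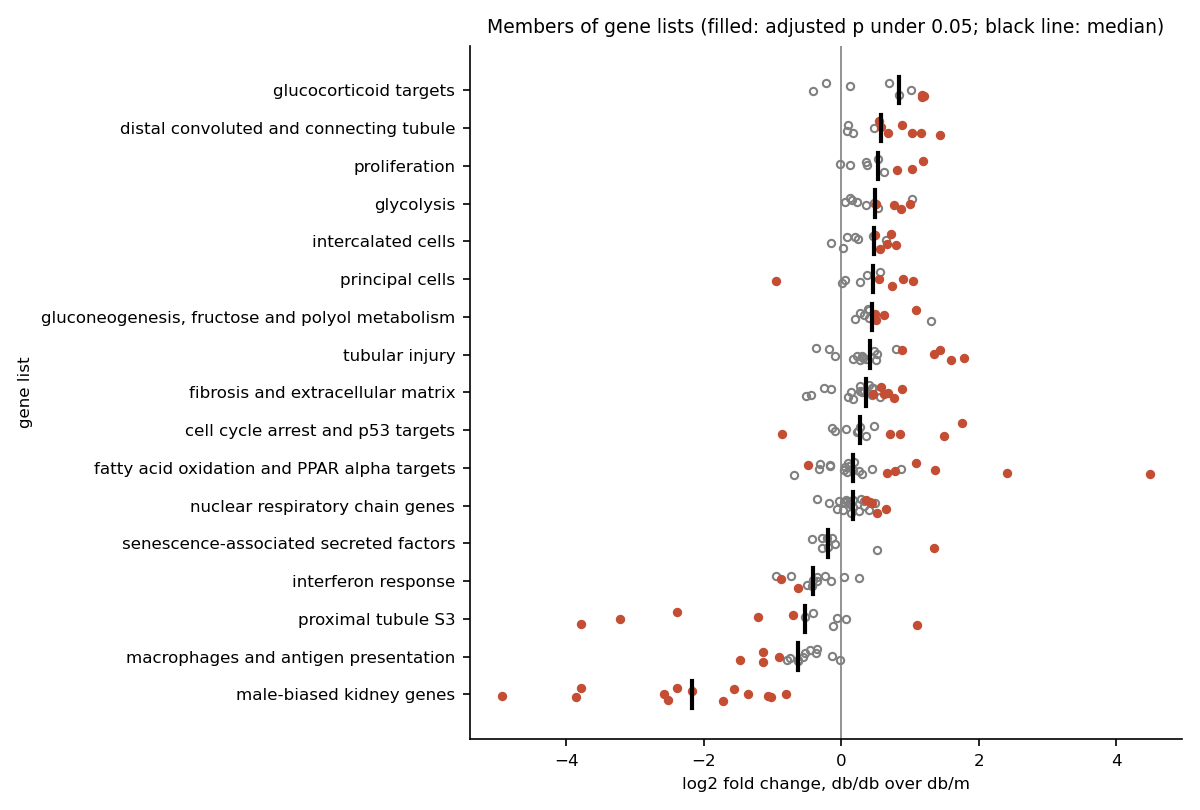
Log2 fold changes (db/db minus db/m) of the tested members of the 16 called lists and of senescence-associated secreted factors, 1 point per gene, filled where the adjusted p was under 0.05, with a black line at each list's median. All 13 male-biased genes lie below 0, around a median of -2.17.

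Tubular injury genes rose in db/db: 5 of 18 were higher (7 adjusted over the list alone). These were complement C3 (1.59, SE 0.20; 20.3 ± 6.22 to 60.9 ± 16.8 CPM), osteopontin Spp1 (1.35, SE 0.17; 55.5 ± 18.7 to 141 ± 33.5 CPM), clusterin Clu (0.88, SE 0.15), lipocalin Lcn2 (1.78, SE 0.34) and fibrinogen Fgg (1.44, SE 0.31). Camera gave an adjusted p of 2.21e-06, and 0.0255 with an estimated correlation. Havcr1, the kidney injury molecule KIM-1, was too low to test, with 18 counts in db/m and 13 in db/db, and Vcam1 was at -0.37 (SE 0.15), not past the threshold.

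Among cell cycle arrest and p53 target genes, the cell cycle inhibitor Cdkn1a (p21) rose from 13.1 ± 5.42 to 44.4 ± 8.79 CPM (1.75, SE 0.21), with Ccng1 (0.85, SE 0.12), Gdf15 (14.8 ± 8.75 to 42.1 ± 27.0 CPM) and Zmat3 (0.71, SE 0.18). Glb1, which encodes the lysosomal beta-galactosidase whose activity is used as a senescence stain, fell from 58.1 ± 6.22 to 32.0 ± 5.01 CPM (-0.86, SE 0.11). In all, 4 of 13 list members rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0177, and 0.0455 with an estimated correlation). Cdkn2a (p16) had 1 count in db/m and 3 in db/db and could not be tested. Of 9 tested secreted factors, Spp1 alone was called (1 adjusted over the list alone), and the list was not (adjusted p = 0.817), with a median of -0.20, a mean of 0.03 and a downward test direction. The other 12 of the 21 listed were too low to test, Il6 with 1 and 0 counts among them. Of 9 proliferation genes 3 rose (5 adjusted over the list alone), including Top2a (1.03, SE 0.25) and Mcm5 (1.19, SE 0.31). This list had a camera adjusted p of 0.000444, and 0.0192 with an estimated correlation.

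Of 22 fibrosis and matrix genes, 6 rose (7 adjusted over the list alone), including the basement membrane collagen Col4a2 (0.58, SE 0.10; 77.4 ± 10.7 to 115 ± 16.7 CPM), Col5a1 (0.89, SE 0.20) and Sparc (0.62, SE 0.16). The fibrillar collagens Col1a1 (0.17, SE 0.34) and Col3a1 (0.15, SE 0.27), fibronectin Fn1 (0.33, SE 0.20) and the myofibroblast actin Acta2 (0.27, SE 0.26) did not pass the test. For this list camera gave an adjusted p of 0.00227, but adjusted p = 0.352 with an estimated correlation, and fry 0.0547. The call of Sparc ended with the 4 libraries that stood apart removed (edgeR adjusted p = 0.0700). The calls of Col4a1 and Fbn1 each ended in 12 of 17 fits that left out 1 library. Markers of stromal and mural cells (0 of 11 called) and endothelium (0 of 14) were not called as lists (camera adjusted p = 0.875 and 0.569), and 0 were called adjusted over the list alone. By edgeR 0 and 2 of these had an unadjusted p under 0.05, and DESeq2 and limma voom called 0.

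**Figure D5:**
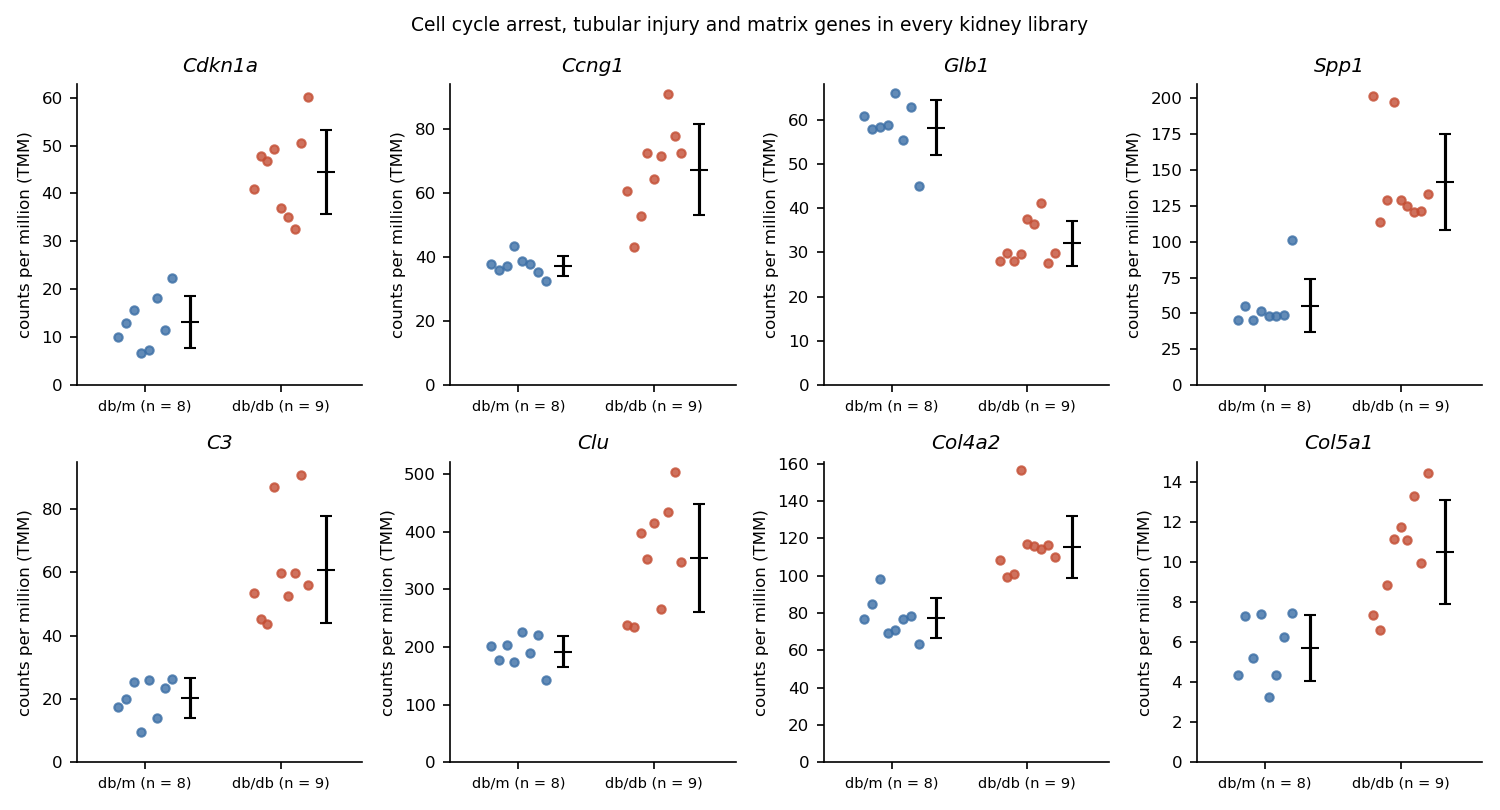
CPM in each library (points) with each group's mean ± SD (n = 8 for db/m, n = 9 for db/db), on linear axes from 0, for Cdkn1a, Ccng1, Glb1, Spp1, C3, Clu, Col4a2 and Col5a1. Cdkn1a goes from 13.1 ± 5.42 to 44.4 ± 8.79 CPM, and Glb1 from 58.1 ± 6.22 to 32.0 ± 5.01.

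The tested macrophage and antigen presentation genes were lower in db/db: 4 of 15 fell (6 adjusted over the list alone) and 15 of 15 had negative values, around a median of -0.63. Among members too low to test, raw counts were higher over db/db for Adgre1 (42 in db/m and 60 in db/db) and Cd14 (69 and 95). They were lower for Cd68 (86 and 69), Itgam (24 and 22) and Ms4a7 (48 and 22). The class II genes H2-Eb1 (86.8 ± 10.3 to 39.3 ± 10.2 CPM), H2-Aa (-1.15, SE 0.22) and H2-Ab1 (-0.90, SE 0.17) and the receptor Clec7a (-1.48, SE 0.27) fell. The list had a camera adjusted p of 1.84e-07, and 0.0255 with an estimated correlation. Of the B and plasma cell genes only 3 could be tested, too few for a list test. Igha and Igkc fell (2 adjusted over the list alone) and Ighm was at -0.46 (SE 0.27). Without db/m replicate 8, Igkc was still lower, at -1.86 (SE 0.39) in place of -2.74. Of 13 interferon response genes 2 fell (5 adjusted over the list alone). Camera gave this list an adjusted p of 0.000444, and 0.0255 with an estimated correlation. The call of Oasl2 ended in 14 of 17 fits that left out 1 library, and 1 member fell in 12. Beside these genes, db/m replicate 8 stood apart in the fat gene Fabp4, at 569 CPM against a median of 24.7 in the other db/m libraries, and in Igkc, at 306 CPM against 43.4. The brown fat gene Ucp1 had 1871 counts over db/m and 320 over db/db and was not tested, and the adipocyte list was not called (median -0.93, camera adjusted p = 0.320, and 0.0498 with the replicate number as a block). Of its 6 genes, edgeR called 0, and 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05, and DESeq2 and limma voom called 0.

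Of 11 genes of the renin-angiotensin and mineralocorticoid systems, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with angiotensinogen Agt (1.10, SE 0.16) and the sodium channel subunit Scnn1a (0.68, SE 0.14) higher and the converting enzyme Ace lower (-1.65, SE 0.13; 28.1 ± 5.31 to 8.96 ± 1.12 CPM). This list was not called (adjusted p = 0.0735, and 0.0420 with GC-adjusted offsets), and 3 members were higher without db/m replicate 4. Of 9 glucocorticoid targets 3 rose (5 and 1 adjusted over the list alone), including Sgk1 (1.21, SE 0.27) and the metallothionein Mt1 (1.17, SE 0.26), whose call ended at an edgeR adjusted p of 0.0590 with the 4 libraries that stood apart removed. The glucocorticoid list had an adjusted p of 0.0331, but adjusted p = 0.389 with an estimated correlation, and fry gave 0.0784. Its call ended without db/m replicate 5 (adjusted p = 0.0921) and without db/db replicate 1, 2, 3 or 4 (adjusted p = 0.0839, 0.0686, 0.0698 and 0.0672). Without db/db replicate 8, 5 of its members rose. Of 12 NRF2 targets, 4 rose and 2 fell (4 and 2 adjusted over the list alone), with the transporter Abcc4 higher (1.23, SE 0.18) and the glutathione synthesis subunit Gclm lower (-0.91, SE 0.15). That list was not called (adjusted p = 0.244), and 1 member fell without db/m replicate 3 or 4. Of 14 podocyte genes, 2 rose and Npr3 (-0.79, SE 0.19) fell (3 and 1 adjusted over the list alone; list adjusted p = 0.358). Only 1 podocyte gene rose in 11 of 17 fits that left out 1 library.

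Of the 37 lists tested, 12 were higher and 4 lower in db/db, and 6 and 4 with an estimated correlation. With the 4 libraries that stood apart removed (db/m replicate 8 and db/db replicates 4, 7 and 8), genes higher in db/db numbered 404, 272 of them shared with the fit of all 17 libraries. The genes lower in db/db numbered 479, 329 of them shared. Lists higher were then 13 (12 shared) and lists lower 4 (4 shared). Within 10 Mb of Lepr, 12 of 98 tested genes were called, against 885 of 12033 elsewhere (odds ratio 1.76, Fisher's exact test, two-sided, p = 0.0778). Within 20 Mb, which takes in the Cyp4a cluster, 27 of 204 were called (odds ratio 1.94, Fisher's exact p = 0.00277), and within 5 Mb 4 of 45 (odds ratio 1.22, Fisher's exact p = 0.573). These windows were counted because the groups differ in the DNA linked to Lepr. Cyp2j13, on the male-biased list, lies within 10 Mb. Cyp4a12a and Cyp4b1 of that list, and Cyp4a14, lie within 20 Mb. Whether linked DNA changed the counts of these genes was not tested.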

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

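For the patterns weighed here, the tests were chosen after the result was seen, except the GC content test of the first component and the counts over other splits of the libraries, which were set before. Values of single libraries that stood far from the rest of their group were sought in 334 groups of values by Dixon's test, and 43 were found; chance alone gives about 1 in 20.

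The male-biased kidney genes fell together, 13 of 13. The tables argue against a loss of S3 cells as the whole cause, since the 9 S3 markers that are not male-biased had a median log2 fold change of only -0.41 (SE 0.29), and against a GC-related library bias, since 13 of 13 stayed lower with GC-adjusted offsets. A weaker male-hormone signal in db/db kidneys may contribute, as a hypothesis: it predicts higher female-biased genes, but these went both ways (median -0.54, SE 1.64, n = 6), which keeps it open. The genotype itself is the biological difference of the design and is also open.

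Antigen presentation and immunoglobulin genes were lower in db/db. Fat or lymph tissue attached to db/m replicate 8 is argued against as the cause for the antigen presentation list, since without that library its median was still -0.62 (camera adjusted p = 1.02e-07). Igkc and Igha also stayed lower without db/m replicate 8, at -1.86 (SE 0.39) and -3.66 (SE 0.35). Dilution by tubule RNA is argued against too: the 39 endothelial, stromal and podocyte markers had a median of 0.11, which lies 0.74 above that of the macrophage list (SE of the difference 0.127). The genotype is the biological difference of the design and stays open, as how it would lower these genes was not tested.

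The first principal component did not follow the groups, and no biological explanation was tested, as the design names none within a group. A GC-related bias goes with it in part (Spearman rho 0.291 between loading and GC content across 12126 genes, which are not independent replicates), but is argued against as the whole cause, since after removal of the GC trend the positions of the 17 libraries correlated with the earlier ones at 0.999. Library depth is argued against (pooled within-group r = 0.105, permutation p = 0.709). An unequal share of proximal tubule in the tissue pieces stays open: within groups the component went with the S1 and S2 score (r = -0.504, permutation p = 0.0470), but past the threshold in only 5 of 17 tests that left out 1 library (r = -0.335, permutation p = 0.210 without db/db replicate 1). Of 7 lists of other kidney cells, 6 had the opposite sign, which this explanation needs of all, and stromal cells did not (r = -0.264, permutation p = 0.326). The component went most strongly with the distal convoluted and connecting tubule (r = 0.619, permutation p = 0.00705) and the thick ascending limb (r = 0.559, permutation p = 0.0299). It hardly went with principal cells (r = 0.0897, permutation p = 0.736) or intercalated cells (r = 0.0540, permutation p = 0.856).

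The counts of called genes were set against 100 splits of the 17 libraries into groups of 8 and 9, the real one included. For genes higher in db/db, 1 split, the real one, gave as many as 474 (highest other 170). For genes lower, 2 splits gave as many as 423 (highest other 737). Chance is thus unlikely for both counts, but 100 splits cannot exclude it, and for lower genes another split gave more. The split with 737 lower genes put 3 db/m and 5 db/db libraries on one side, with mean positions on the first component of -19.8 and 17.6, which points to a structure of the libraries along that component. For lists higher, 1 split, the real one, gave as many as 12, but the highest other gave 11, so chance is unlikely but not excluded. That other split had 6 db/m libraries on its first side, so it kept much of the real contrast. For lists lower, 31 splits gave as many as 4 (highest other 11, with 4 db/m libraries on its first side), so chance cannot be excluded for that count. Splits with few db/m libraries on the first side turn part of the real contrast round. A split with 2 there, for example, gave 6 lists higher and 8 lower. The 31 is therefore not a rate of chance alone. The other splits had a median of 2 lists higher and 2 lower. Camera thus also called lists in groups that mixed db/m and db/db, though some of these groups kept part of the real contrast.

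In db/m replicate 8, the number of genes detected was high at 19328 and its position on the second component low for its group at -3.63. Its CPM was high for Maob (3.64), Igkc (306), Spp1 (101), Pdgfra (22.99), Cidea (131.4), Fabp4 (569), Car3 (351), Nqo1 (13.8) and Btg2 (21.1). In db/db replicate 8, the mean Spearman correlation with the other libraries was low at 0.889, and the scores of fatty acid oxidation (0.914) and of the renin-angiotensin list (0.846) were high. Its CPM was high for Igkc (36.2), Cyp4a12a (170.2), Sparc (518), Eng (145), Pi16 (13.5), Gpam (218), Pdia4 (48.2) and Atf4 (335). In db/db replicate 9, the gene count was high at 7627747, as were the scores of adipocytes (1.546) and interferon response (0.528) and the CPM of Cidea (30.04), Car3 (312), Hbb-bt (784) and Alas2 (70.1).

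In db/db replicate 1, the secreted factor score (0.816) and the CPM of Bhmt (22.6), Slco1a1 (37.1) and Mlxipl (173) were high and that of Slc38a3 (27.0) was low. In db/m replicate 7, the podocyte score (0.559) and the CPM of Per1 (44.6) were high. High CPM values also stood out for Gsta2 in db/db replicate 3 (146), Col4a2 (156) and H2-Ab1 (81.8) in db/db replicate 4, Cyp7b1 in db/db replicate 6 (22.9), Ier2 in db/db replicate 7 (6.81) and Akr1c14 in db/m replicate 4 (48.6). The proliferation score of db/m replicate 2 was high at 0.166.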

How the results depend on the processing

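Of the settings given here, GC-adjusted offsets and the removal of 4 libraries were chosen after the data were seen; the others were set before the data were examined. Of 6048 pairs of a gene and an alternative, 0 reversed, 471 lost the call and 47 gained one. Of the 137 called genes tried, 60 kept the call in every alternative, 82 in every alternative but the stricter thresholds, and 104 without any 1 library. A gene that the count filter of an alternative left out was counted as kept there. Grem1, for example, was tested in only 9 of the 17 fits that left out 1 library. Of 37 lists, 26 kept their side of the threshold in every alternative, with 0 reversals. The counts of genes higher in db/db and genes lower in db/db moved by over 1.5 times with 1 surrogate variable (719 and 677), an adjusted p under 0.01 (205 and 230), an absolute log2 fold change of at least 1 (128 and 167), and the replicate number as a block (200 and 235). The numbers do not pair the animals: correlations of same-numbered libraries ran from -0.454 to 0.212, 2 of 8 were over 0.1, and 0 db/m libraries correlated best with their own number. Lists higher went from 12 to 6 with an estimated correlation. The Nnmt correlation with tubular injury in db/m fell to r = 0.139 (exact permutation p = 0.735) without 2 libraries, and the odds ratio near Lepr was 1.94 (Fisher's exact p = 0.00277) with a window of 20 Mb; the cause of these moves was not tested. With 1 library left out, higher genes ran from 319 to 666, lower genes from 318 to 571, lists higher from 11 to 13, lists lower from 4 to 5, and Nnmt from -0.27 to 0.15. GC-adjusted offsets gave 482 and 422 genes (434 and 371 shared), and DESeq2 621 and 534.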

Other observations

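The genes outside the fixed lists and the muscle markers in this part were chosen after the data were seen, and the tests of lists before. Several abundant metabolic genes outside the fixed lists also differed. In db/db, Acy3, an aminoacylase, fell from 3572 ± 541 to 979 ± 262 CPM (log2 fold change -1.87, SE 0.16), Ldhd, which oxidises D-lactate, from 870 ± 169 to 219 ± 42.8 CPM (-1.99, SE 0.14), and the adipokine Azgp1 from 130.3 ± 23.2 to 25.6 ± 4.76 CPM (-2.35, SE 0.13). The fatty acid transporter Cd36 fell (-1.93, SE 0.20; 77.2 ± 10.2 to 20.06 ± 7.89 CPM), whereas Kif23, a motor protein of cell division, rose (2.04, SE 0.21; 4.98 ± 1.22 to 20.5 ± 6.75 CPM). Inmt, another methyltransferase that uses S-adenosylmethionine, fell from 1785 ± 267 to 809 ± 175 CPM (-1.14, SE 0.13).

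Lists not described so far were not called by camera: heat shock (adjusted p = 0.0915), immediate early genes (0.196), unfolded protein response (0.302), red blood cells (0.320), complement (0.320), circadian clock (0.540), mitochondrially encoded genes (0.548) and lipogenesis (0.728). In lipogenesis 2 of 11 genes fell (1 higher and 2 lower adjusted over the list alone), Me1 among them (-1.28, SE 0.20), but only 1 fell in 14 of 17 fits that left out 1 library. Of 11 heat shock genes 1 fell (4 adjusted over the list alone), of 15 unfolded protein response genes 1 rose (1 adjusted over the list alone), and of 10 complement genes C3 rose (1 higher and 2 lower adjusted over the list alone). For immediate early genes, red blood cells, circadian clock and mitochondrially encoded genes, edgeR called 0 members, and 0 adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 1, 2 and 0. DESeq2 called 1 clock gene and 0 of the others, and limma voom 0. By edgeR, 0 heat shock genes fell without db/m replicate 1, 2 or 4, and 2 without db/m replicate 8 or db/db replicate 1 or 5. Likewise 0 unfolded protein response genes rose without db/m replicate 1, 3, 4 or 6 or db/db replicate 4, and 2 without db/db replicate 1. Without db/m replicate 8 the immediate early list was higher (camera adjusted p = 0.0313), as it was with the 4 libraries that stood apart removed (0.0160). Without db/m replicate 4 or 6 the heat shock list was lower (adjusted p = 0.0440 and 0.0331). The lists of T and NK cells, granulocytes and adrenal gland had 0 tested members.

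Skeletal muscle transcripts, 11 markers listed after the component loadings were seen, made up 567 CPM in db/m replicate 1 and 475 CPM in db/m replicate 7, against 8.91 to 128 CPM in the other libraries (scaled to gene counts alone).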
